A study of Homo sapiens with 6 samples.

How the data were processed

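RNA-sequencing libraries of 6 samples of U251 cells were analysed, 3 labelled as controls and 3 as TEAD3 knockdown. U251 is an established human glioma cell line. Per the labels' protocols, the knockdown was made by transient transfection. The labels name both a plasmid vector and an siRNA, and do not say what the controls received. Polyadenylated RNA was captured on oligo(dT) beads, converted to strand-marked libraries by the dUTP method and sequenced as paired reads, per the labels' protocols. The labels do not say that the replicates came from separate cultures, so every p-value measures the spread between these libraries, which may be technical.

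The authors deposited whole-number counts per gene, with no scaling for library size. Per the submitters' processing notes, the tools were cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2 and edgeR, with genome build GRCh38. Which of them wrote the deposited counts, the annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. The counts may therefore be rounded coverage-based estimates. Genes with near-identical copies, and genes whose exons overlap another gene on either strand, are reported as uncertain for this reason. The count table held 60612 Ensembl gene identifiers, of which 60401 matched a symbol and 211 did not. Coordinates and overlaps were taken from GENCODE release 29, which is on GRCh38.

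The total count was 63685272, 58344026 and 59631029 in control replicates 1 to 3 and 63145768, 64459583 and 64808615 in knockdown replicates 1 to 3. At this depth 3 counts correspond to between 0.0463 and 0.0514 CPM (counts scaled by library total), a floor that covers counting error only. No pair of libraries agreed within counting noise: chi-square per degree of freedom between libraries of one group lay between 22.7 and 80.6. Between libraries of different groups it lay between 42.1 and 96.1, so the ranges overlapped.

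All computations were made from the deposited counts in R 4.3.3. Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 with TMM normalisation, two-sided, with group as the only term and Benjamini-Hochberg adjustment. In the text, edgeR adjusted p stands for the result of this test, and a gene is called when it is under 0.05. The filterByExpr function with its default minimum of 10 counts left 17723 of the 29520 genes that had at least 1 count. Levels are TMM-normalised CPM, given as mean ± SD over the 3 libraries of a group. Fold changes are knockdown over control on the log2 scale, with a standard error (SE) from the fitted model.

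Gene lists, 31 in all, were fixed before the data were examined, as were the design, the rule for naming genes and most alternatives. The 29 lists with at least 5 tested genes were compared with all other genes by camera in limma 3.58.1, with its preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. In the text, camera adjusted p stands for this test. Because the preset value can be too small for genes that are regulated together, camera was repeated with a correlation estimated from the data, and fry was run as a test of each list against no change. The genes named are TEAD3, 8 others fixed by name, the 8 largest called changes in each direction with an average log2 CPM of at least 3, no overlap between groups and a gene symbol, and up to 3 called members of each list with the smallest adjusted p. Other genes, where named, were chosen after their values were seen, and this includes the uncalled or further members given as examples of a list.

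The procedure was tested on simulated counts with 200 changed genes among 17194 genes in the fit, with the depths and spread of this comparison. edgeR recovered 25.4% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 95.5% of those changed 4-fold, with 10 false calls among 144. On the same data DESeq2 recovered 46.3%, 91.0% and 95.5%, with 36 false calls among 191, and limma-voom 23.9%, 80.6% and 95.5%, with 14 false calls among 147. The changed genes were drawn only from genes with higher expected counts, and each gene was simulated independently. These rates therefore need not hold for genes with low counts or where many genes shift together in a library. The common biological coefficient of variation was 0.227.

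Alternatives fixed at the same time were DESeq2 size factors, upper-quartile scaling and library size alone, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, leaving out mitochondrial and the 10 most abundant genes, an adjusted p under 0.01, and a test against a 1.5-fold change. Chosen after seeing the data were robust quasi-likelihood dispersions, a per-library loess correction for transcript length and GC content, and a covariate for non-polyadenylated RNA. The loess correction used a span of 0.3 over 11610 genes, and 98.8% of tested genes had a length and GC value. Length and GC content were those of the longest annotated transcript of each gene, which need not be the one expressed. The covariate was the mean log2 CPM of RN7SL1, RN7SL2, RN7SK, RPPH1 and RMRP in each library. All 6 libraries entered the comparison, and no per-sample column was left out.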

Results

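Polyadenylated RNA was sequenced from U251 glioma cells, an established human line, in 3 control libraries and 3 libraries made after knockdown of TEAD3. TEAD3 encodes a TEAD family transcription factor, a DNA-binding partner of the coactivators YAP1 and TAZ (the product of WWTR1) at the output of the Hippo pathway. The comparison asked which transcripts differed in level after the knockdown. Mitochondrial transcripts took between 7.61% and 8.96% of the counts. The first principal component, with 26.6% of the variance, placed all 3 control libraries on one side and all 3 knockdown libraries on the other.

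TEAD3 transcript fell to 34% of the control level (95% interval 24.4% to 47.5%). TEAD3 (ENSG00000007866) lies on GRCh38 chromosome 6 from 35473597 to 35497076 on the minus strand. Its level was 14.9, 20.3 and 21 CPM in control replicates 1 to 3 and 4.70, 8.35 and 6.08 CPM in knockdown replicates 1 to 3, so each knockdown library lay below each control. The means were 18.7 ± 3.34 and 6.38 ± 1.84 CPM (SD, n = 3 each), a log2 fold change of -1.55 with SE 0.218 (edgeR adjusted p = 0.0114). TEAD3 was not called without control replicate 3 (-1.46, edgeR adjusted p = 0.0541), knockdown replicate 1 (-1.37, 0.0532) or knockdown replicate 3 (-1.52, 0.0938). It was also not called when no filter on low counts was used (-1.56, edgeR adjusted p = 0.0639) or with the covariate for non-polyadenylated RNA (-1.45, 0.0569).

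None of the other TEAD genes or the 2 coactivators was called. TEAD1 was at 76.3 ± 12.2 CPM in controls and 70.0 ± 3.74 CPM in the knockdown, a log2 fold change of -0.12 (edgeR adjusted p = 0.69), and this became 0.0066 without control replicate 1 and -0.23 without control replicate 2 (0.99 and 0.215). TEAD2 had a log2 fold change of 0.05 (edgeR adjusted p = 0.85) and TEAD4, the least abundant at 7.26 ± 1.11 CPM in controls, of 0.16 (0.746). TEAD2 was at 0.0086, 0.11 and 0.08 without control replicates 1 and 2 and knockdown replicate 1, and TEAD4 at 0.28, 0.08 and 0.04 without control replicates 2 and 3 and knockdown replicate 2. The upper 95% bounds of the fold change were 1.11, 1.2 and 1.47 for TEAD1, TEAD2 and TEAD4, so a rise of up to these sizes was not excluded. YAP1 was at 98.3 ± 10.1 and 84.0 ± 4.12 CPM (log2 fold change -0.23, edgeR adjusted p = 0.333). WWTR1 was at 83.7 ± 10.9 and 59.7 ± 4.65 CPM (-0.49, edgeR adjusted p = 0.0995). WWTR1 was called without control replicate 2 (-0.60, edgeR adjusted p = 0.0234), with the length and GC correction (-0.46, 0.0172) and by DESeq2 (adjusted p = 0.00574). In the list of 24 TEAD family and Hippo pathway genes, which includes the other TEAD genes, YAP1 and WWTR1, 17 had a fold change below 0 and none was called by edgeR. There were 1 higher and 5 lower at an unadjusted p under 0.05, and DESeq2 called 2 lower. WWTR1 and the kinase gene LATS1 were the 2 genes lower when adjusted over the list alone. The list median was -0.17 (camera adjusted p = 0.0137), and the call was lost with an estimated correlation (adjusted p = 0.439), without control replicate 1 (-0.10, adjusted p = 0.0876) and with the non-polyadenylated RNA covariate (-0.11, adjusted p = 0.069).

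**Figure D1:**
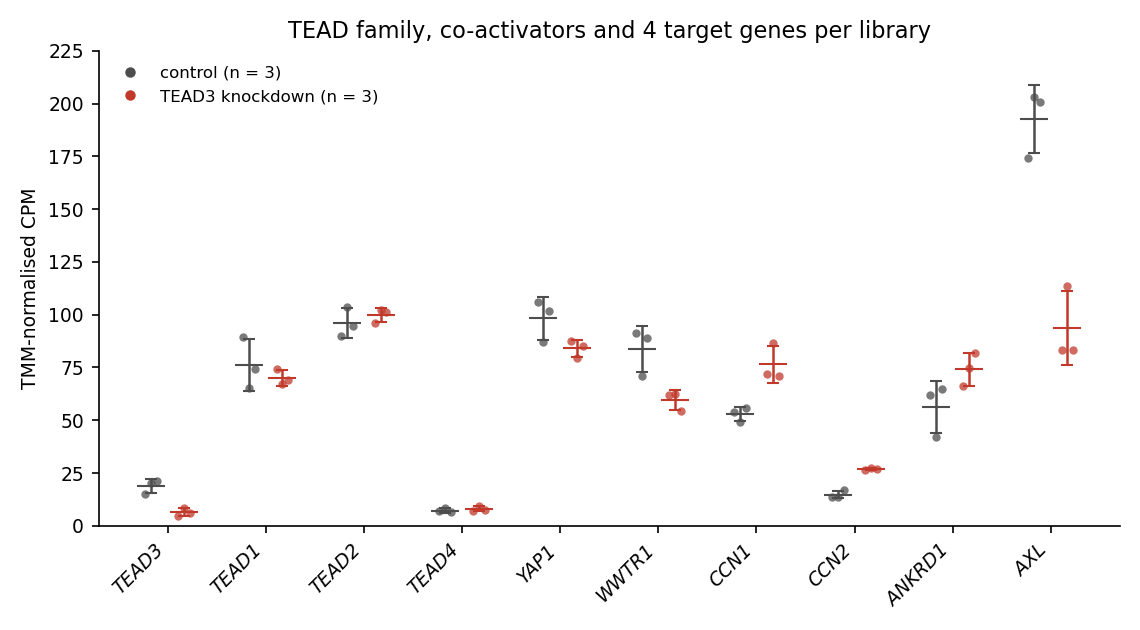
Levels of the TEAD genes, their coactivators and 4 known target genes in TMM-normalised CPM (vertical axis) for the 3 control (grey) and 3 TEAD3 knockdown (red) libraries, with points for libraries, horizontal bars for means and whiskers for SD. TEAD3 was 18.7 CPM in controls and 6.38 CPM in the knockdown, CCN2 rose from 14.8 to 27.0 CPM and AXL fell from 193 to 93.5 CPM.

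Known YAP/TAZ-TEAD target genes did not move together. Of 22 tested, AXL fell and CCN2 rose, and 20 were not called. There were 4 higher and 5 lower at an unadjusted p under 0.05, and DESeq2 called 3 higher and 1 lower. With the length and GC correction edgeR called 2 higher and 2 lower. AXL, which encodes a receptor tyrosine kinase, went from 193 ± 15.9 to 93.5 ± 17.5 CPM (log2 fold change -1.04, SE 0.134, edgeR adjusted p = 0.00646). CCN2, which encodes a secreted matricellular protein and is among the most used reporters of YAP activity, went from 14.8 ± 1.72 to 27.0 ± 0.55 CPM (0.87, SE 0.125, edgeR adjusted p = 0.0137). Adjusted over the list alone, 3 were higher, CCN2, CCN1 and GADD45A, and 1 was lower, AXL. CCN1, a paralog of CCN2, was at 52.9 ± 3.39 and 76.6 ± 8.73 CPM (0.53, edgeR adjusted p = 0.0656) and ANKRD1 at 56.3 ± 12.2 and 74.2 ± 7.90 CPM (0.40, edgeR adjusted p = 0.255, and 0.23 without control replicate 2). CCN1 was called without control replicate 2 (0.48, edgeR adjusted p = 0.0456), with the stricter filter (0.0438), with robust dispersions (0.0388), with the length and GC correction (0.0198) and by DESeq2 (adjusted p = 0.000911). The list median was -0.09 (camera adjusted p = 0.709, and 0.846 with an estimated correlation), and it was -0.03 without control replicate 3, -0.04 without knockdown replicate 1 and 0.03 with the non-polyadenylated RNA covariate. AXL was not called without knockdown replicate 1 (-0.96, edgeR adjusted p = 0.0509) or 3 (-0.97, 0.0697), and CCN2 was not called without knockdown replicate 1, 2 or 3 (0.88, 0.85 and 0.87, with edgeR adjusted p of 0.0704, 0.0539 and 0.113) or with the non-polyadenylated RNA covariate (0.91, 0.0579).

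Across 17723 genes tested, 116 were called (0.655%), 80 higher and 36 lower in the knockdown. At least 2-fold changes were found for 51 of them, 44 higher and 7 lower. In all 116 the control and knockdown libraries did not overlap, which was the case for 21.6% of all tested genes where chance alone gives 10%. At an unadjusted p under 0.05 there were 2761 genes. Every library weighed on the count: it was 58, 589 (259 higher and 330 lower) and 43 without control replicates 1, 2 and 3, and 29, 73 and 20 without knockdown replicates 1, 2 and 3, with the at least 2-fold count at 25 and 20 without knockdown replicates 1 and 3. DESeq2 called 872 genes (488 higher and 384 lower), among them 114 of the 116 in the same direction. Control replicates 1 and 2 stood apart in opposite directions, with Spearman correlations between their deviations and GC content of -0.569 and 0.683. The other libraries lay between -0.234 and 0.196. Correlations of the deviations with transcript length were 0.305, -0.0975 and 0.262 in control replicates 1 to 3. In knockdown replicates 1 to 3 they were -0.303, -0.116 and -0.0396, so control replicate 2 lay among the knockdown libraries and length did not separate the groups. Fold changes followed transcript length, with a Spearman correlation across 10970 protein-coding genes, which are not independent replicates, of -0.253. Correction for length and GC content removed this trend (-0.00595) and gave 553 calls, 269 higher and 284 lower, with 115 of the 116 among them, so that the share of higher calls was 48.6% where it had been 69%.

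Among called genes with a symbol, an average log2 CPM of at least 3 and no overlap between groups, the largest increase was in SCG2, which encodes secretogranin II, a protein of secretory granules. Genes known only by an identifier were not ranked, among them ENSG00000267952 (0.322 ± 0.203 CPM in controls and 0.819, 32.1 and 25.5 CPM in knockdown replicates 1 to 3), ENSG00000284292 (19.9 ± 11.5 CPM in controls and 0 in each knockdown library) and ENSG00000248431 (-0.88). Exons of ENSG00000284292 overlap those of ARPC1A and ARPC1B on the same strand and of PDAP1 on the opposite strand. Its counts, the zeros included, are therefore uncertain. SCG2 went from 2.96 ± 0.658 to 24.1 ± 4.57 CPM, 8.13-fold (log2 fold change 3.02, SE 0.203, edgeR adjusted p = 0.000181). CA9, a hypoxia-induced carbonic anhydrase gene, rose from 3.01 ± 1.43 to 13.3 ± 3.94 CPM, and RGS2, a regulator of G-protein signalling, from 19.5 ± 2.37 to 60.3 ± 6.56 CPM. DHRS2, a short-chain dehydrogenase gene, rose from 12.7 ± 0.494 to 36.3 ± 3.93 CPM, and AKR1C1, an aldo-keto reductase gene with close paralogs, from 6.30 ± 1.21 to 20.8 ± 5.84 CPM. Their log2 fold changes were 2.14, 1.63, 1.51 and 1.72 (edgeR adjusted p of 0.0169, 0.000304, 0.000304 and 0.00646). The remaining 3 of the 8 largest increases within these limits were the histone genes H2AC6, H4C15 and H4C14. Besides TEAD3 and AXL, the largest decreases within the same limits were in PADI3 (peptidylarginine deiminase, 108 ± 32.4 to 46.5 ± 4.68 CPM), CNR1 (cannabinoid receptor, 169 ± 24.4 to 79.5 ± 4.51), CPA4 (carboxypeptidase, 151 ± 17.6 to 82.3 ± 20), the keratin genes KRT15 (156 ± 21 to 86.2 ± 8.95) and KRT13 (44.0 ± 5.19 to 25.0 ± 2.90), and MXD3, a MYC-network repressor gene (28.1 ± 4.85 to 15.7 ± 0.70). Their log2 fold changes were -1.22, -1.09, -0.88, -0.85, -0.81 and -0.84 (edgeR adjusted p of 0.0169, 0.00242, 0.0367, 0.0137, 0.021 and 0.0283). SCG2, RGS2, DHRS2, AKR1C1, CNR1 and the 3 histone genes were called whichever library was left out.

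Calls among the other large changes ended when some libraries were left out, with no change of direction. CA9 was not called without control replicate 3 (edgeR adjusted p = 0.0893) or knockdown replicates 1 and 3 (0.0866 and 0.112), and PADI3 was not called without knockdown replicates 1 and 3 (0.112 and 0.139). CPA4 was not called without control replicates 1 and 3 (edgeR adjusted p of 0.107 and 0.0859) or knockdown replicates 1 and 3 (0.165 and 0.261). For KRT15 the call ended without knockdown replicates 2 and 3 (edgeR adjusted p of 0.0539 and 0.13). For KRT13 it ended without control replicate 1 (edgeR adjusted p = 0.062) and without knockdown replicates 1, 2 and 3 (0.0577, 0.0622 and 0.166), and for MXD3 in the same fits (0.0811, then 0.13, 0.0926 and 0.188). With no filter on low counts 31 genes were called, and CA9, PADI3, CPA4, KRT15, KRT13 and MXD3 were not among them. With the non-polyadenylated RNA covariate 23 genes were called, which included CA9 but not AKR1C1, PADI3, CPA4, KRT15, KRT13 or MXD3. Exons of CA9, KRT13, CCN2, AXL, YAP1, WWTR1, TEAD2, KIF2C, SLC7A5, TNFRSF12A, H4C14 and H4C15 overlap a gene on the opposite strand, those of KRT15 overlap one on the same strand, and those of MXD3, DDIT3 and ELF3 overlap genes on both, and their counts are uncertain where strand was not used.

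**Figure D2:**
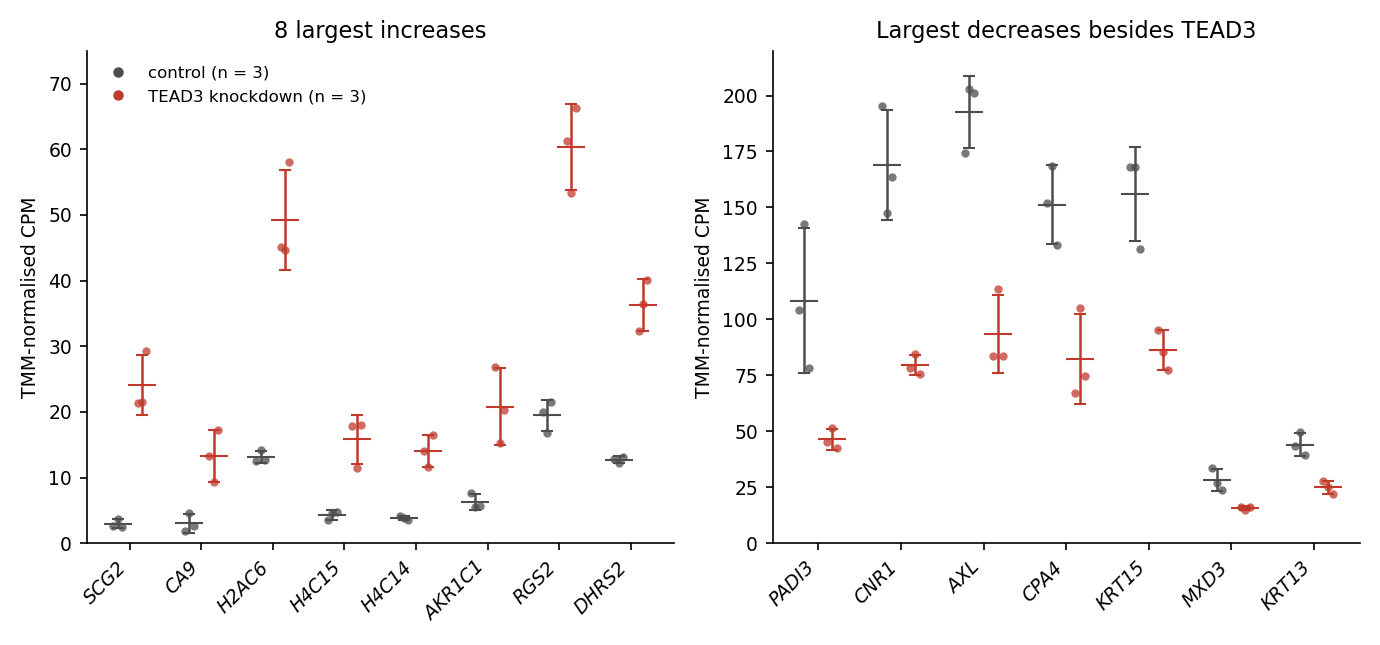
Levels in TMM-normalised CPM (vertical axes) of the 8 genes with the largest increases (left) and of the genes with the largest decreases besides TEAD3 (right) among called genes with a symbol, an average log2 CPM of at least 3 and no overlap between groups, in 3 control (grey) and 3 TEAD3 knockdown (red) libraries, with points for libraries, horizontal bars for means and whiskers for SD. SCG2 rose from 2.96 to 24.1 CPM and CNR1 fell from 169 to 79.5 CPM, and for each gene drawn the groups do not overlap.

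Transcripts of replication-dependent histones, which end in a stem-loop and mostly lack a poly(A) tail, rose as a group in these libraries. Capture on oligo(dT) beads selects for a poly(A) tail, so the total level of histone transcripts need not have risen. Of 16 tested, 3 rose and none fell: H2AC6 from 13.2 ± 0.889 to 49.2 ± 7.62 CPM (log2 fold change 1.9, edgeR adjusted p = 0.000181), H4C14 from 3.82 ± 0.279 to 14 ± 2.41 CPM (1.87, 0.00113) and the linker histone gene H1-2 from 11.3 ± 0.767 to 29.2 ± 3.67 CPM (1.38, 0.00129). The other 13 were not called, and 7 were higher when adjusted over the list alone. H4C15, a near-identical copy of H4C14 outside the list, rose from 4.31 ± 0.697 to 15.8 ± 3.72 CPM (1.88, edgeR adjusted p = 0.00345), and the split of reads between the 2 copies is uncertain. The list median was 1.24 (camera adjusted p = 3.62e-15), and this was the only one of the 29 lists called with an estimated correlation (adjusted p = 0.0362). Together with the length and GC correction that call was lost (adjusted p = 0.205), at a median of 0.95. Other RNAs without a poly(A) tail, RN7SL1, RN7SL2, RN7SK and RPPH1, were above every control in knockdown replicates 1 and 3 and not in knockdown replicate 2, while RMRP was above every control only in knockdown replicate 3. RN7SL1, the RNA of the signal recognition particle, was at 14.7, 34.5 and 17.6 CPM in the controls and at 60.8, 14.4 and 79.8 CPM in knockdown replicates 1 to 3, and was not called (1.22, edgeR adjusted p = 0.264).

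**Figure D3:**
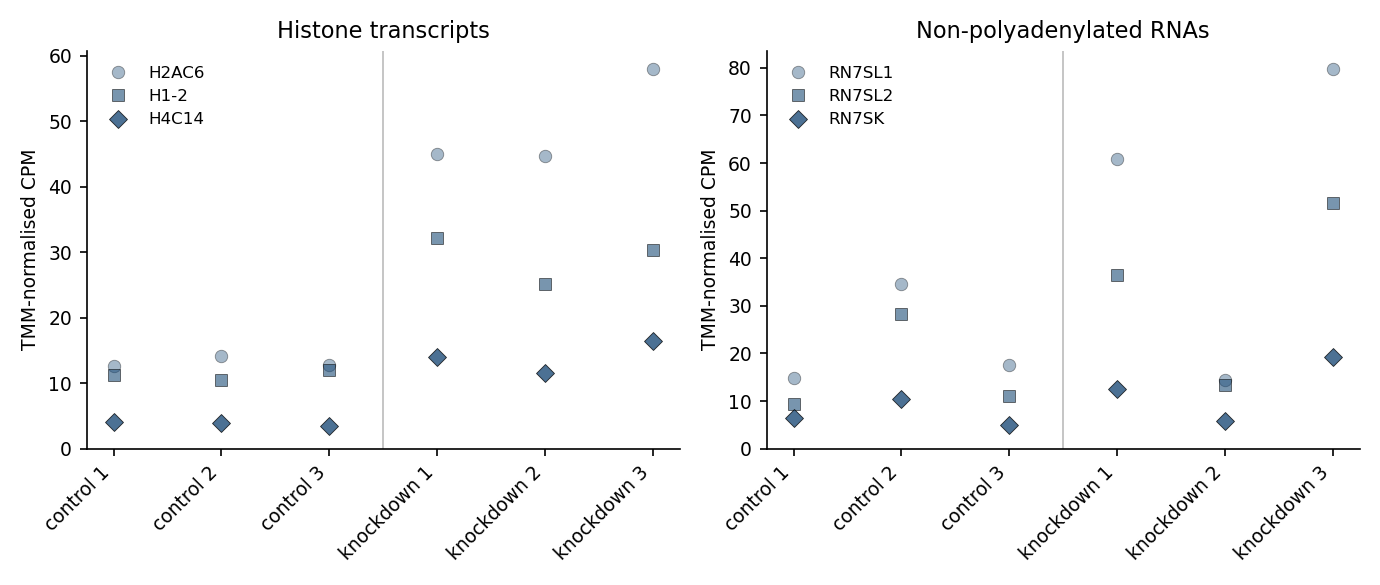
Levels in TMM-normalised CPM (vertical axes) of 3 histone transcripts (left) and 3 RNAs without a poly(A) tail (right) in each of the 6 libraries (horizontal axis), each point being the value of one library. H2AC6 was 44.6 CPM in knockdown replicate 2, above the highest control at 14.2 CPM, where RN7SL1 was 14.4 CPM, below each control at 14.7 CPM or more.

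Transcripts of cytosolic ribosomal proteins had fold changes above 0 for 40 of the 40 tested genes, with no gene called by edgeR, against 35 at an unadjusted p under 0.05 and 20 by DESeq2. Their median was 0.35 and 34 were higher when adjusted over the list alone, among them RPS23 (0.54, edgeR adjusted p = 0.0919) and RPL5 (0.37, 0.101). The camera adjusted p was 1.13e-21, but the members varied together between libraries with an estimated correlation of 0.701, and with that correlation the call was lost (p = 0.0928, adjusted p = 0.439). Nuclear-encoded genes of oxidative phosphorylation had a median of 0.19, with 29 of 34 above 0 and none called by edgeR over all genes or adjusted over the list alone (camera adjusted p = 0.000177, and 0.534 with an estimated correlation). At an unadjusted p under 0.05 there were 8 higher, and DESeq2 called 2 higher. Without knockdown replicate 1 this list was not called (0.09, camera adjusted p = 0.0515). Taken from the longest annotated transcript of each gene, which need not be the one expressed, the median transcript length of the ribosomal protein genes was 1849 nucleotides. The tenth of protein-coding genes with the shortest transcripts, up to 1693 nucleotides, had a median log2 fold change of 0.16 and the tenth with the longest, from 7819 nucleotides, of -0.07, and random lists with the lengths of the ribosomal protein genes had a typical median of 0.08. After the length and GC correction the medians of the ribosomal protein and oxidative phosphorylation lists were 0.28 and 0.08. Transcripts of the mitochondrial genome had a median of 0.08, with none of 15 called by edgeR, 1 at an unadjusted p under 0.05, 1 by DESeq2 and 1 higher when adjusted over the list alone (camera adjusted p = 0.131). This list was called without control replicate 2 (0.16, camera adjusted p = 0.0151) and without knockdown replicates 1 and 3 (0.15 and 0.14, 0.0127 and 0.0311), and its median was 0.0054 without control replicate 1 and -0.03 without knockdown replicate 2. It was called as higher with the non-polyadenylated RNA covariate (0.14, camera adjusted p = 0.0327) and as lower with the length and GC correction (-0.11, 0.047).

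**Figure D4:**
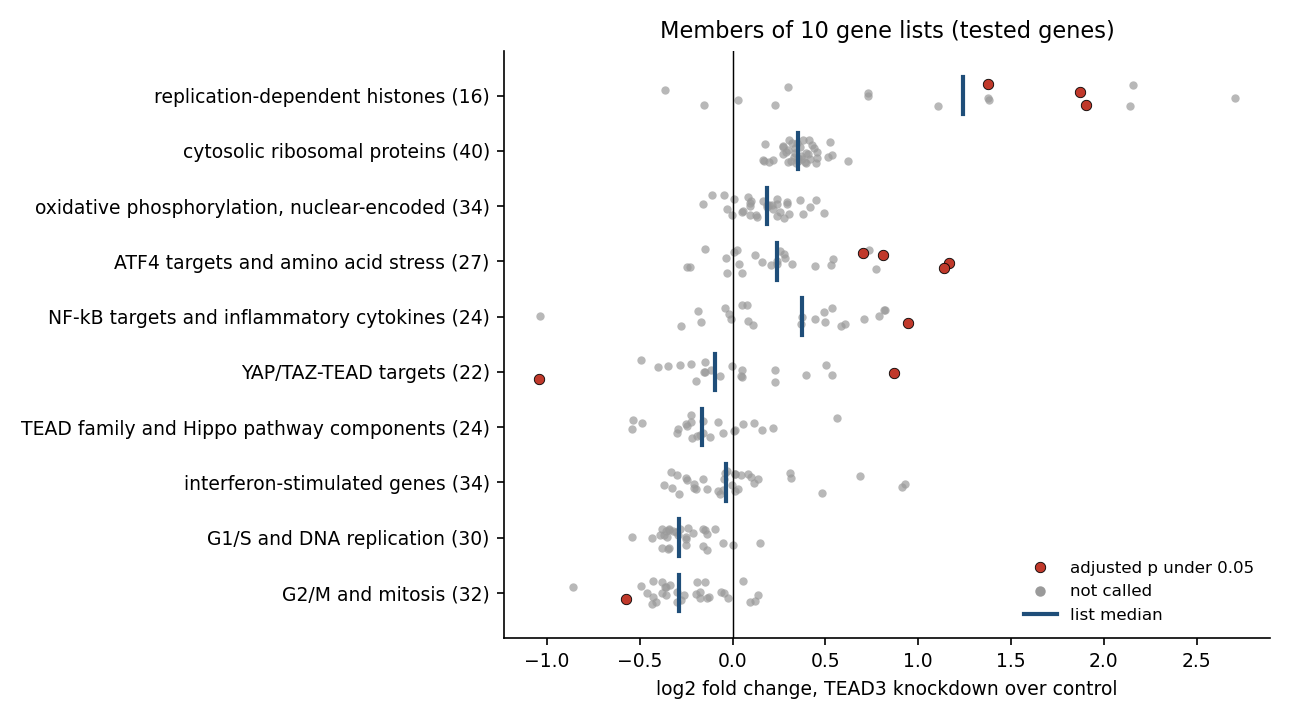
Log2 fold change of TEAD3 knockdown over control (horizontal axis) for the tested members of 10 gene lists (rows, number of genes in brackets), with a point for each gene, red for called genes, and a blue line at the list median. Histones had a median of 1.24, ribosomal proteins of 0.35 and both cell cycle lists of -0.29, and the YAP/TAZ-TEAD targets spread to both sides of 0.

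Targets of ATF4, the transcription factor of the amino acid and integrated stress response, were higher as a list with the preset correlation, a call that was lost with an estimated one. Of 27 tested, 4 rose, none fell and 23 were not called, and 9 were higher when adjusted over the list alone. SLC3A2 and SLC7A5, whose products form the large neutral amino acid transporter, went from 170 ± 17.0 to 381 ± 50.4 CPM (log2 fold change 1.17, edgeR adjusted p = 0.00211) and from 51.2 ± 9.34 to 113 ± 15.1 CPM (1.14, 0.00646). DDIT3, which encodes the stress factor CHOP, went from 51.8 ± 2.55 to 90.7 ± 10.4 CPM (0.81, edgeR adjusted p = 0.00931), and NUPR1 was the remaining called member (0.70, 0.029). The list median was 0.24 (camera adjusted p = 1.37e-10), with an adjusted p of 0.041 by fry, and the call was lost with an estimated correlation (p = 0.00997, adjusted p = 0.145). SLC7A5 was not called without knockdown replicate 3 (edgeR adjusted p = 0.0559), and DDIT3 was not called without knockdown replicate 1 or 3 (0.0577 and 0.0697). Both were not called with the non-polyadenylated RNA covariate (edgeR adjusted p of 0.0503 and 0.0703), while SLC3A2 was called whichever library was left out. The chaperones of the endoplasmic reticulum, which belong to another arm of the stress response, had a median of -0.01 with none of 19 called by edgeR, 1 lower at an unadjusted p under 0.05 and none by DESeq2 (camera adjusted p = 0.844).

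Inflammatory and immediate early genes were higher as lists with the preset correlation, calls that were lost with an estimated one, and few or no members were called. Among 24 tested NF-kB targets and inflammatory cytokines 1 rose, RELB, which encodes an NF-kB subunit (19.0 ± 4.35 to 36.5 ± 6.63 CPM, log2 fold change 0.94, edgeR adjusted p = 0.0429), and 4 were higher when adjusted over the list alone, RELB, CXCL8, NFKB2 and TRAF1. The list was fixed with 25 members, and the other one matched no symbol. ENSG00000112096, which had no symbol and was not tested in the list, shares exons on the same strand with SOD2, a fixed member. It was called higher (64.0 ± 7.88 to 107 ± 14.5 CPM, 0.74, edgeR adjusted p = 0.0297), so the count of 1 may be too low. The list median was 0.37 (camera adjusted p = 0.0036), and the call was lost with an estimated correlation (adjusted p = 0.439) and without knockdown replicate 2 (0.26, adjusted p = 0.0833), and the median was 0.22 without control replicate 3. None of 21 immediate early genes was called by edgeR, 6 were higher at an unadjusted p under 0.05 and 3 by DESeq2. EGR1, MYC and MAFF were the 3 higher when adjusted over the list alone. Their median was 0.21 (camera adjusted p = 0.0156, and 0.461 with an estimated correlation), and the list was not called without control replicate 1 (0.16, 0.0876) or knockdown replicate 2 (0.18, 0.0754). Of 17 MAPK feedback genes DUSP4, a MAP kinase phosphatase gene, rose (39.4 ± 7.42 to 67.4 ± 4.62 CPM, 0.77, edgeR adjusted p = 0.0315), and 2, DUSP4 and DUSP1, were higher when adjusted over the list alone. The MAPK feedback list had a median of 0.10 (camera adjusted p = 0.176) and was called without knockdown replicate 1 (0.17, 0.049) and with the length and GC correction (0.21, 0.0356), with medians of 0.05, 0.20 and 0.05 without control replicates 1 and 2 and knockdown replicate 2. RELB was called in only 1 of the 6 fits that left out a library, without control replicate 2, with edgeR adjusted p of 0.132 and 0.192 without control replicates 1 and 3 and of 0.134, 0.061 and 0.278 without knockdown replicates 1, 2 and 3. DUSP4 likewise had edgeR adjusted p of 0.113, 0.165, 0.134, 0.061 and 0.214 in those fits. Neither gene was called without a filter (edgeR adjusted p of 0.143 and 0.109) or with the non-polyadenylated RNA covariate (0.169 and 0.161).

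Hypoxia and glycolysis genes had a median of 0.12 over 30 tested, of which CA9 rose and 29 were not called. Adjusted over the list alone, 3 were higher, CA9, the peptide hormone gene ADM and NDRG1. The camera adjusted p of 0.0426 became 0.534 with an estimated correlation, 0.23 and 0.146 without control replicates 1 and 3 (medians of 0.06 and 0.06), and 0.0873 and 0.0877 without knockdown replicates 2 and 3. This list was also not called with limma-voom (adjusted p = 0.054), without the most abundant genes (0.0569) or with the non-polyadenylated RNA covariate (0.186).

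Genes of the cell cycle were lower as lists with the preset correlation, calls that were lost with an estimated one. Of 30 genes of the G1/S transition and DNA replication 29 had a fold change below 0 and none was called by edgeR over all genes. At an unadjusted p under 0.05 there were 19 lower, DESeq2 called 8 lower, and edgeR with the length and GC correction called 7 lower. Adjusted over the list alone 14 were lower, with TYMS (239 ± 22.0 to 165 ± 22.0 CPM, log2 fold change -0.54, edgeR adjusted p = 0.0719), CDC6 (-0.38, 0.119) and MCM3 (-0.36, 0.126) as examples. Of 32 genes of G2/M and mitosis KIF2C fell and 31 were not called, and 12 were lower when adjusted over the list alone, among them CCNA2 (-0.46, edgeR adjusted p = 0.106) and TOP2A (-0.43, 0.115). In this list 18 were lower at an unadjusted p under 0.05, DESeq2 called 9 lower, and edgeR with the length and GC correction called 8 lower. KIF2C, which encodes a microtubule-depolymerising kinesin, went from 115 ± 3.05 to 77.0 ± 10.5 CPM (-0.57, edgeR adjusted p = 0.0493). The medians of both lists were -0.29, with camera adjusted p of 2.60e-10 and 1.63e-09. Both calls held whichever library was left out, and both were lost with an estimated correlation (p of 0.0426 and 0.0867, adjusted p of 0.412 and 0.439). KIF2C was not called without control replicates 1 and 3 (edgeR adjusted p of 0.143 and 0.205) or knockdown replicates 1 and 3 (0.246 and 0.311), nor with DESeq2 size factors (0.0513), upper-quartile scaling (0.0503), library size alone (0.0539), no filter (0.13) or the non-polyadenylated RNA covariate (0.275).

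Genes of the extracellular matrix and the mesenchymal state differed in direction. Of 29 tested, 2 rose, none fell and 27 were not called: TGFBI, an extracellular matrix protein gene induced by TGF-beta, from 67.7 ± 8.24 to 118 ± 2.71 CPM (log2 fold change 0.80, edgeR adjusted p = 0.00913), and FBN1, the gene of fibrillin-1, from 16.5 ± 1.48 to 29 ± 4.59 CPM (0.81, 0.0312). Among the members higher when adjusted over the list alone were these 2, COL4A1 and THBS1, while VIM (-0.29, edgeR adjusted p = 0.2) and COL1A2 (-0.32, 0.202) were not called. The list median was -0.00018, where its mean was 0.15 and camera gave the direction up (adjusted p = 0.0418). The call was lost with an estimated correlation (adjusted p = 0.439), without control replicate 1 (0.213), without knockdown replicates 2 and 3 (0.174 and 0.0877), with the stricter filter (0.0687), with limma-voom (0.0859) and with the non-polyadenylated RNA covariate (0.069). TGFBI was not called without knockdown replicates 1 and 3 (edgeR adjusted p of 0.0577 and 0.0697) or with that covariate (0.0548). FBN1 was not called without control replicates 1 and 3 (edgeR adjusted p of 0.0825 and 0.155), knockdown replicates 1 and 3 (0.13 and 0.227), a filter (0.103) or with the covariate (0.209).

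Genes of the actin cytoskeleton and focal adhesion had a median of -0.13, with none of 26 called by edgeR over all genes or adjusted over the list alone, against 1 higher and 3 lower at an unadjusted p under 0.05 and 1 higher by DESeq2 (camera adjusted p = 0.0373, and 0.534 with an estimated correlation). This list was not called without control replicates 2 and 3 (-0.10 and -0.14, camera adjusted p of 0.303 and 0.06), without knockdown replicate 1 (-0.09, 0.25) or with the stricter filter (-0.11, 0.0687). Its median was -0.23 without control replicate 1 and -0.21 without knockdown replicate 2. The RNAi machinery and cytosolic nucleic acid sensors had a median of -0.18 with none of 17 called by edgeR and none adjusted over the list alone, against 1 higher and 5 lower at an unadjusted p under 0.05 and 1 lower by DESeq2 (camera adjusted p = 0.0485, and 0.461 with an estimated correlation). That call ended without control replicates 1 and 3 (camera adjusted p of 0.165 and 0.108), without knockdown replicates 1, 2 and 3 (0.134, 0.0754 and 0.0554), with upper-quartile scaling (0.0524), without the most abundant genes (0.0514), with the length and GC correction (0.254) and with the non-polyadenylated RNA covariate (0.211).

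Markers of glioma cell states were not called as lists. Of 19 mesenchymal-like genes TNFRSF12A, the gene of the TWEAK receptor, rose from 64.8 ± 11.5 to 109 ± 12.4 CPM (log2 fold change 0.75, edgeR adjusted p = 0.0387) and was the 1 gene higher when adjusted over the list alone, at a list median of 0.06 (camera adjusted p = 0.13). The list was called without control replicate 2 (0.16, camera adjusted p = 0.0151), and its median was 0.0046 without control replicate 1. TNFRSF12A was not called without control replicates 1 and 3 (edgeR adjusted p of 0.109 and 0.165), without knockdown replicates 1, 2 and 3 (0.146, 0.0642 and 0.266), without a filter (0.13) or with the non-polyadenylated RNA covariate (0.192). Of 12 astrocyte-like genes none was called by edgeR, 2 were higher and 1 lower at an unadjusted p under 0.05 and 1 higher by DESeq2. SLC1A3 and FABP7 were higher and GFAP lower when adjusted over the list alone (median 0.10, mean -0.07, direction up, camera adjusted p = 0.852, with medians of 0.04 and 0.03 without control replicate 3 and knockdown replicate 3). Of 10 progenitor-like genes none was called by edgeR, 1 was higher and 4 lower at an unadjusted p under 0.05 and 1 lower by DESeq2. DLL3 was higher and PDGFRA lower when adjusted over the list alone (median -0.17, mean 0.04, direction down, camera adjusted p = 0.337, with medians of -0.26 and -0.09 without knockdown replicates 1 and 2).

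Markers of other cell types served as a check on the composition of the samples. Of 8 epithelial markers ELF3, an epithelial transcription factor gene, fell from 47.7 ± 6.03 to 30.9 ± 1.98 CPM (log2 fold change -0.63, edgeR adjusted p = 0.0471), and 2, ELF3 and CLDN4, were lower when adjusted over the list alone. The epithelial median was -0.36 (camera adjusted p = 0.0373, and 0.461 with an estimated correlation), and the list was not called without control replicate 2 (-0.37, 0.124), without knockdown replicate 2 (-0.28, 0.17) or with limma-voom (0.0563), and its median was -0.15 without control replicate 1. ELF3 was not called without control replicates 1 and 3 (edgeR adjusted p of 0.113 and 0.0962), knockdown replicates 1, 2 and 3 (0.151, 0.108 and 0.304) or a filter (0.123), nor with upper-quartile scaling (0.0533) or the non-polyadenylated RNA covariate (0.169). None of 8 neuron markers was called by edgeR, 1 was higher and 1 lower at an unadjusted p under 0.05 and 1 higher by DESeq2. The neurofilament gene NEFL was the 1 gene higher when adjusted over the list alone (median -0.0023, mean -0.10, direction up, camera adjusted p = 0.928). None of 5 fibroblast markers was called by edgeR or by DESeq2, or adjusted over the list alone, and 2 were higher at an unadjusted p under 0.05 (median 0.01, camera adjusted p = 0.571). Only 3 haematopoietic and 3 endothelial markers passed the filter, too few for a list test, and none was called by edgeR or DESeq2 or adjusted over the list alone. At an unadjusted p under 0.05 there was 1 endothelial marker, higher.

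The remaining lists held no called gene and were not called. Interferon-stimulated genes had a median of -0.04 and a mean of 0.02 over 34 genes, with the direction down (camera adjusted p = 0.557; medians of -0.07, 0.0082 and -0.0048 without control replicate 2 and knockdown replicates 2 and 3), and none passed when adjusted over the list alone. There were 5 higher and 7 lower at an unadjusted p under 0.05, and DESeq2 called 1 higher and 3 lower. Heat shock proteins had a median of -0.08 over 16 genes (camera adjusted p = 0.108), and this list was called without control replicate 2 (-0.11, 0.0262), with no filter (0.0415) and with the length and GC correction (0.00533). The medians were -0.0015 over 23 genes of cholesterol biosynthesis (camera adjusted p = 0.775), 0.00067 over 24 p53 targets (0.852), -0.02 over 24 apoptosis regulators (0.593) and 0.29 over 11 Wnt targets (0.844). The Wnt median was 0.01 without control replicate 2, and 0.12 and 0.17 without knockdown replicates 1 and 3. Adjusted over the list alone, 1 of these genes was higher, the p53 target PLK3. At an unadjusted p under 0.05 edgeR found 2 heat shock, 2 cholesterol, 5 p53, 5 apoptosis and 1 Wnt gene, and DESeq2 called 2 p53 targets and 1 gene of cholesterol biosynthesis.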

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

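Of the alternatives, the robust fit, the length and GC correction and the non-polyadenylated RNA covariate were chosen after seeing the data, and the others before that. Of the 116 genes called, 31 remained with no filter on low counts, where 31 genes were called and 21 at 2-fold or more, 107 with the stricter filter (186 called), 114 with DESeq2 (872 called, 106 at 2-fold or more), 112 with the robust fit (197), 115 with the length and GC correction (553) and 22 with the covariate (23 called, 19 at 2-fold or more). An adjusted p under 0.01 left 27, and a test against a 1.5-fold change 10, both by construction stricter. Leaving out 1 library gave 20 to 589 calls and 20 to 71 at 2-fold or more. The cause of the shifts other than under the stricter tests was not tested. The 3 other scalings called 106 to 115 genes and moved the median of all genes by 0.0015, 0.0087 and -0.011, and limma-voom called 120. Depth limited the test to 17723 of the 29520 genes with a count.

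With the replicate number as a block 63 genes were called (57 of the 116), 37 at 2-fold or more, with a TEAD3 log2 fold change of -1.58. Of the named genes CA9, MXD3, KIF2C, RELB, FBN1, DUSP4, TNFRSF12A and ELF3 were not called with the block, nor were the hypoxia list and the list of RNAi machinery and nucleic acid sensors. The labels do not say whether the numbers pair the samples. Same-numbered libraries deviated from their group means with correlations of 0.0056, -0.017 and 0.0083 across genes. No shared deviation was thus seen, which does not exclude a shared day. Control replicate 1 correlated more with knockdown replicate 2 (0.972) than with knockdown replicate 1 (0.968). Control replicates 2 (0.9695 against 0.9667) and 3 (0.9705 against 0.9663) did so too, so this cannot decide on pairing.

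TEAD3 was not called with no filter (-1.56) or the covariate (-1.45), and ranged from -1.80 to -1.37 over the 6 fits that left out a library. The YAP/TAZ-TEAD target median, not called under any alternative, ranged from -0.11 to -0.032 over those fits and was 0.027 with the covariate. Of 612 values of single named genes 506 kept direction and side of the threshold, 97 lost the call, 8 gained it and 1 changed sign: TEAD1, which ranged from -0.23 to 0.0066 over the fits that left out a library. Of 558 values of the other lists 442 kept both, 57 lost the call, 10 gained it and 49 changed sign.

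The extracellular matrix median, -0.00018, was 9.8e-05 with DESeq2 size factors, 0.0075 with upper-quartile scaling, 0.074 with no filter, 5.8e-05 with DESeq2, 0.042 with limma-voom, 0.043 with the replicate block, 0.00038 without the most abundant genes, 0.0602 with the length and GC correction, 0.017 with the covariate and 0.00031 to 0.16 over the fits that left out a library. The cholesterol median was 0.00046 with DESeq2 size factors, 0.0079 with upper-quartile scaling, 0.0033 with the stricter filter, 0.00044 with DESeq2, 0.0052 with limma-voom, 0.0079 with the block, 0.0022 with the length and GC correction, 0.023 with the covariate and -0.043 to 0.037 without a library. The neuron median was 0.0067 with upper-quartile scaling, 0.0035 with the stricter filter, 0.0012 with the block, 0.039 with the length and GC correction, 0.0056 with the covariate and -0.085 to 0.056 without a library. The p53 median was -0.0085 with library size alone, -0.063 with the length and GC correction, -0.031 with the covariate and -0.028 to 0.089 without a library. With the length and GC correction the medians were 0.014 for endoplasmic reticulum chaperones, -0.11 for mitochondrial transcripts and -0.053 for mesenchymal-like genes. Without a library they ranged from -0.016 to 0.027 for the chaperones, from -0.028 to 0.16 for mitochondrial transcripts and from -0.046 to 0.21 for fibroblast markers. The ranges were -0.067 to 0.0082 for interferon-stimulated genes and -0.074 to 0.011 for apoptosis regulators. The cause of these sign changes was not tested.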

Other observations

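The tests of carry-over, of S phase, of one knockdown library as the whole source and of another TEAD, the length and GC correction and the covariate were chosen only after the results were seen, as were the snoRNA host group and the single genes named in the next 2 paragraphs.

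Some host genes of small nucleolar RNAs, whose spliced transcripts are short-lived and mostly untranslated, rose in the knockdown. Of 17 such genes with sufficient counts 15 had a fold change above 0 and 4 rose: SNHG1 from 41.8 ± 4.78 to 79.8 ± 6.44 CPM (log2 fold change 0.93, edgeR adjusted p = 0.00646), GAS5 from 108 ± 10.9 to 185 ± 28.9 CPM (0.77, 0.0273), ZFAS1 from 82.0 ± 5.10 to 139 ± 17.7 CPM (0.76, 0.0167) and SNHG15 from 25.6 ± 2.44 to 41.0 ± 3.53 CPM (0.68, 0.0315). The median of the 17 was 0.47, and 0.24 after the length and GC correction. Other genes that rose were IDO1 and KYNU, both of the kynurenine pathway of tryptophan breakdown (1.03 and 1.67, edgeR adjusted p of 0.0024 and 0.00646), the heme oxygenase gene HMOX1 (0.68, 0.0177) and MICA, a ligand of an activating natural killer cell receptor (0.72, 0.0109).

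Interferon-stimulated genes were abundant in the control cells. In the controls 29 of 34 exceeded 100 CPM and their median level was 555 CPM, against 14.4 CPM for all tested genes. IFIT1 was at 4082 ± 493 CPM and IFITM1 at 4015 ± 826 CPM, and 10 of the 34 were among the 100 most abundant genes. Together they took 3.13 ± 0.0681% of counts in controls and 3.00 ± 0.0961% in the knockdown (SD, n = 3 each). IFNB1, the gene of interferon beta, rose from 0.555 ± 0.0995 to 1.99 ± 0.511 CPM (log2 fold change 1.84, edgeR adjusted p = 0.0367) while edgeR called none of the 34, against 12 at an unadjusted p under 0.05 and 4 by DESeq2.

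For the histone transcripts, whose median was higher in each knockdown library than in any control, the level of non-polyadenylated RNA was used as a covariate: their median was 0.952 where it had been 1.24, and H2AC6, H4C14 and H1-2 were still called (edgeR adjusted p of 0.000631, 0.0093 and 0.0168), which argues against carry-over of such RNA as the whole source. A larger share of cells in S phase would raise the genes of DNA replication, but the G1/S median was -0.29. After the length and GC correction the histone median was 0.95, with 12 members above 0 and 4 below, and the same 3 members were called. This argues against that trend, as measured on the longest annotated transcripts, as the whole source. The call of the list with an estimated correlation was lost, for a cause that was not tested: per-library medians were -0.484 ± 0.101 and 0.497 ± 0.0844 before the correction and -0.367 ± 0.13 and 0.381 ± 0.0903 after it (camera adjusted p = 0.205). An effect of the knockdown stays open as an untested hypothesis.

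The ribosomal protein transcripts were raised most in knockdown replicate 1. After the length and GC correction their median was 0.275 where it had been 0.353, with all 40 above 0. Of 10000 random lists matched on transcript length the highest median was 0.239. Both used the longest annotated transcript of each gene, and the random lists lack the correlation between the ribosomal protein genes. The length trend may therefore account for part of the shift, and whether it accounts for the whole cannot be told from these values. Without knockdown replicate 1 the median was 0.239, which leaves open how much that library contributed. Both other knockdown libraries lay above every control, by 0.24 with SE 0.055 on average. The closest were knockdown replicate 2 at 0.0282 and control replicate 2 at -0.093 (0.0156 and -0.0758 after the correction). With so few libraries and genes that vary together, this argues only weakly against knockdown replicate 1 as the whole source. With an estimated correlation the list was called neither before nor after the correction (camera p of 0.0928 and 0.0842), and an effect of the knockdown stays open as untested.

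CCN2 rose and AXL fell, though both are taken as genes that YAP, TAZ and TEAD activate. After the length and GC correction CCN2 was at 0.859 (edgeR adjusted p = 0.00629) and AXL at -0.961 (0.00276), which argues against that trend as the source, while CCN2 was not called with the non-polyadenylated RNA covariate (0.913, 0.0579). A higher level of another TEAD transcript may contribute and stays open: TEAD1, TEAD2 and TEAD4 were not called, but the highest upper 95% bound of their fold change was 1.47, for TEAD4, the least abundant. Summed TEAD CPM was 198.3 ± 2.54 in controls and 184.3 ± 2.29 in the knockdown (SD, n = 3 each). The loss of TEAD3 was thus not made up in the summed level of these libraries, in which TEAD1 and TEAD2 weigh most. Taken singly, the upper 95% bounds of the fold change of TEAD1 and TEAD2 were 1.11 and 1.2, so a rise in either is not excluded. TEAD3 made up 9.47 ± 1.79% of summed TEAD CPM in controls and 3.45 ± 0.955% in the knockdown (SD, n = 3 each; not corrected for transcript length). An effect of TEAD3 itself that differs between targets remains among the open explanations, as untested, and so does a response to transfection, since the labels do not say what the controls received.

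The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real values were reached in 1 of the 10 splits, the real one: 116 genes called against 7 in the highest other split, 51 against 6 at 2-fold or more, and 14 lists called with the preset correlation against 10. The other splits called between 3 and 10 lists.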
